A study of Bos taurus with 9 samples.

How the data were processed

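The series holds 9 one-colour Affymetrix bovine arrays of cultured nucleus pulposus cells, taken per the labels from caudal intervertebral discs of young calves. Per the labels' protocols, the cells were plated in DMEM with fetal bovine serum and left untreated, or given salt to a final osmolality of 500 mOsm/kg for 5 h or 24 h. Total RNA was isolated on columns with DNase treatment, primed with an oligo(dT)-T7 primer and labelled with biotin by in vitro transcription, per the labels' protocols. Each of the 3 groups has 3 arrays, which the labels call biological replicates numbered 1 to 3. The labels do not say whether the cultures came from different animals, so p-values measure the spread between these cultures. The control label gives no time, and the same 3 control arrays serve both time points. Changes with time in culture therefore cannot be told apart from changes with salt.

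The deposited values are intensities on a linear scale, made by the authors with the PLIER algorithm in Affymetrix Expression Console, per the submitters' processing notes; versions and settings are not given in the sources used here. The table has 24128 probe sets, of which 112 are control probe sets of the manufacturer. Values run from 0 upward and include 3620 exact zeros outside those controls. The median intensity of an array was between 67.1 and 84.5, and its 75th percentile between 310.4 and 345.925. No further normalization was applied, as fixed before the data were examined, and the sources used here do not say whether the authors normalized the arrays. Gene symbols came from the platform annotation supplied with the table. Of the 24016 probe sets outside the controls, 13292 carry 1 gene symbol, 86 carry several and 10638 are not listed with a gene in that annotation. Of the listed probe sets, 13283 were matched by gene number to a current table of bovine genes, and the match changed 0 symbols. No gene is named from a probe set with several symbols. Genome positions were not used here.

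Intensities were transformed as log2(value + 16). This pseudocount compresses changes of dim probe sets, so a log2 change is understated where 1 group lies near the floor. The highest intensity of an array was between 13521.7 and 15435.1, and probe sets near it may be saturated, so their changes may be understated too. Probe sets with a mean below the 25th percentile were left out, which left 18012. Group means were fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), so that the 3 groups share an estimate of spread. The comparisons were 5 h minus control, 24 h minus control and 24 h minus 5 h. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, and every adjusted p given for a gene comes from this limma test unless another is named. The number of arrays limits the precision.

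Before the data were examined, 26 gene lists and 9 lists of markers of other cell types were fixed, along with the groups, the tests, the alternatives and the rule for naming genes. Each gene in a list was represented by the single-gene probe set with the highest mean, and 32 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the 32 lists. Each list was also tested with a correlation estimated from the data, and no list was called in this form of the test in any comparison. The estimate was 0.49 for DNA replication, 0.68 for mitosis, 0.41 for ribosome biogenesis and 0.39 for cholesterol synthesis, above the preset 0.01. It was 0.20 for heat shock, 0.21 for the unfolded protein response, 0.079 for cytokines, 0.24 for fibrous matrix and 0.34 for oxidative phosphorylation. The camera p of these lists at the preset may therefore be too small. For the osmoprotective and interferon lists the estimate was -0.021 and -0.022, below the preset. Their unadjusted camera p at 24 h still rose, from 0.00065 to 0.012 and from 0.0066 to 0.026. A higher correlation was therefore not what ended the calls of those lists. Counts of called members are given at the threshold over all probe sets and, where stated, adjusted over the list alone.

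The rule for named genes took, for each time point against control, the 12 genes with the greatest rise and the 12 with the greatest fall among called single-gene probe sets, and 8 and 8 for 24 h minus 5 h. Each had to have all 3 arrays of 1 group beyond all 3 of the other and a mean in the higher group at or above the median of all probe sets, with placeholder symbols left out and the brightest probe set of a gene used. Genes fixed by name included SLC5A3, SLC6A12, SLC6A6, AKR1B1, NFAT5, SGK1, ATP1B1, HSPA1A, CDKN1A, GADD45A, ACAN, COL2A1 and SOX9. Of these, SLC5A3, SLC6A12, NFAT5 and SOX9 had no single-gene probe set in the annotation used and were not analysed here. From each list, up to 4 called members with the smallest adjusted p were also named.

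The groups share replicate numbers in the labels. Deviations of arrays from their group means correlated between 0.56 and 0.90 across probe sets for arrays of the same number, and between -0.78 and 0.54 for arrays of different numbers. In 18 of 18 comparisons of an array with another group, the best match had its own number. The numbers therefore pair the arrays, although the labels do not say what a number stands for. The fit written before the data were examined has no block; values of a fit with the replicate number as a block are given beside counts and beside the printed results of genes and lists whose call it changed.

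The scripts were tested on simulated data with the real means and spread, in which 200 of the 18012 probe sets differed at 24 h from control. With the residual spread within groups as independent noise, changes of 0.585, 1 and 2 on the log2 scale were recovered for 2.99%, 26.9% and 78.8% of the changed probe sets, with 4 false calls. With simulated replicate effects and no block, as in the reported fit, the shares were 0%, 22.4% and 77.3%, with 0 false calls. Adding the block to that fit, they were 37.3%, 77.6% and 97.0%, with 6 false calls. The alternatives tried were the replicate block, a pseudocount of 1, quantile normalization, arrays centred on their medians, no filter, a filter at the 50th percentile, eBayes without a trend, fits to the 6 arrays compared, array weights, other choices of probe sets, a threshold of 2-fold, other forms of the list test and each array left out in turn. Leaving out all 3 arrays numbered 3, and joining the estimated correlation to the block, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.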

Results

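Expression was measured in bovine nucleus pulposus cells, the cells of the gelatinous core of the intervertebral disc, on 9 arrays. There were 3 arrays of untreated cells, 3 of cells held at 500 mOsm/kg with salt for 5 h and 3 of cells held there for 24 h. Per the design text of the series, the question was how transcript levels respond to hyperosmotic stress at these times. In a principal component analysis, component 1 held 47.7% of the variance and set the 3 arrays numbered 3, 1 from each group, apart from the other 6. Component 2 held 31.1% and set the 24 h arrays apart from the control and 5 h arrays. Control replicate 1 had a component 2 score of 0.011, between the 24 h arrays and the other control arrays, which scored 22.3 and 29.6.

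**Figure D1:**
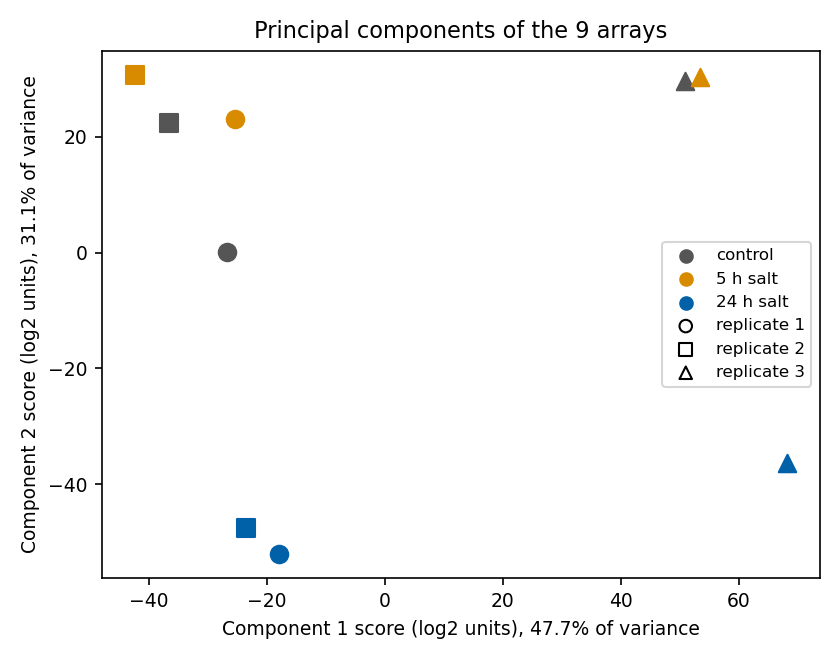
Scores of the 9 arrays on the first principal components of log2(intensity + 16), with component 1 on the x axis and component 2 on the y axis. Colour gives the group and symbol the replicate number; arrays numbered 3 lie at component 1 scores of 50.8 to 68.1, and the 24 h arrays at component 2 scores of -52.0 to -36.3.

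After 5 h in salt, the secreted Wnt antagonist DKK1 rose by 2.81 ± 0.42 on the log2 scale (SE, 3 arrays per group), from an intensity of 45.5 ± 9.3 (SD) in control to 464.3 ± 239, and the chemokine gene GRO1 rose by 2.74 ± 0.42, from 367 ± 203 to 2391 ± 692. The background potassium channel KCNK5 rose by 2.46 ± 0.24 from an intensity of 18.6 ± 3.5, and the semaphorin SEMA4A by 2.29 ± 0.33 from 11 ± 1.1, both near the floor in control. A second SEMA4A probe set, about as dim, stood at 0.71 with adjusted p = 0.59. Transcription factor genes were among the genes that rose, with log2 changes of 2.02 for MEOX2, 1.91 for OSR2, 1.62 for NFIL3 and 1.34 for HOXA4. The inositol phosphate kinase IP6K2 rose by 2.11, the ubiquitin ligase RNF19B by 1.32, the chromatin remodeller CHD2 by 1.26 and the coactivator PNRC1 by 1.05. Adjusted p for these 12 genes ranged from 0.0044 (IP6K2 and OSR2) to 0.038 (GRO1 and HOXA4). The probe sets of IP6K2 differed in size, at 2.11, 1.44, 0.46 and 0.22, and only the first pair were called. Dimmer probe sets of DKK1 (1.93), OSR2 (0.64 and 1.12), NFIL3 (1.65), CHD2 (0.98 and 0.48) and PNRC1 (1.0 and 0.99) were not called.

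The proto-oncogene MYC fell by 2.16 ± 0.17 on the log2 scale at 5 h, from an intensity of 777 ± 119 to 160 ± 15 (adjusted p = 0.0025). The sodium-phosphate cotransporter SLC20A1 fell by 1.74 ± 0.14, from 2465 ± 122 to 732 ± 118 (adjusted p = 0.0025), and NAT1 fell by 2.23 ± 0.15 (adjusted p = 0.0015). The pseudokinase gene TRIB1 fell by 2.26, TCIM by 2.55 and KCTD11 by 1.73, and ANKRD49 had a log2 change of -2.09. The transcriptional repressor BHLHE40 fell by 1.64, the deadenylase subunit CNOT6 by 1.42, the microRNA-processing enzyme DICER1 by 1.24, the Notch glycosyltransferase LFNG by 1.24 and LIPT1 by 1.22. Adjusted p for these genes was at most 0.043 (TCIM). Dimmer probe sets of TRIB1 (-1.04), BHLHE40 (-1.28) and LFNG (-0.048) were not called.

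Genes of osmotic protection rose as a list at 5 h, with a median log2 change of 0.12 and camera adjusted p = 0.0068. Of 9 measured members 1 was called, the amino acid transporter SLC38A2, which rose by 0.88 ± 0.12 (adjusted p = 0.030); 2 rose when adjusted over the list alone. The list's adjusted p was 0.39 with an estimated correlation and 0.059 with the replicate block. Aldose reductase, AKR1B1, which makes the osmolyte sorbitol, had a log2 value of 0.40 ± 0.19 at 5 h with adjusted p = 0.74, and 0.028 with the replicate block. HSPA1A stood at 0.996 ± 0.25 with adjusted p = 0.20, and 0.041 with the block. Heat shock proteins and chaperones shifted up as a list, with a median of 0.16 (camera adjusted p = 0.0045, 0.84 with an estimated correlation) and 0 of 22 members called, either over all probe sets or adjusted over the list alone. Mitosis genes had a median of 0.18 (camera adjusted p = 0.0033, 0.997 with an estimated correlation) with 0 of 31 called. Over the 60 genes of the mitosis and DNA replication lists, the median change at 5 h was 0.46, 0.039 and -0.11 in replicate pairs 1, 2 and 3. The upward shift over these genes thus lay mainly in pair 1. At an unadjusted p under 0.05, 489 probe sets were higher and 810 lower at 5 h. Cytokines, chemokines and NF-kB targets had a median of 0.11 (camera adjusted p = 0.016, 0.84 with an estimated correlation and 0.057 with the replicate block), and 1 of 32 members, GRO1, rose; 2 did so adjusted over the list alone. Of 21 immediate early genes, IER3 rose by 0.69 and MYC fell, and the list was not called (camera adjusted p = 0.42). Under the replicate block, 3 osmoprotective, 2 heat shock, 0 mitosis and 3 cytokine genes rose, and 3 immediate early genes rose and 5 fell.

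In all, 42 probe sets were higher and 45 lower at 5 h than in control of 18012 tested, and with the replicate block 442 and 614. The 87 calls were all kept under the block. With each array centred on its median, 34 were higher and 23 lower. Leaving out an array of any group lowered the total to between 15 and 26, except that it was 61 without 24 h replicate 3 and 126 without 5 h replicate 2. Fitted to the 6 arrays compared, 7 were higher and 6 lower. Of 26 genes named for 5 h and called there, 7 kept their call with each array left out in turn: KCNK5, IP6K2, OSR2, NAT1, MYC, ANKRD49 and SLC20A1. The list calls ended without control replicate 2 or 5 h replicate 3 for the osmoprotective genes (highest adjusted p = 0.072) and the cytokine list (0.23), without control replicate 3 or 5 h replicate 2 for the heat shock list (0.18), and without control replicate 1 for mitosis, whose median was then -0.048 (adjusted p = 0.93).

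After 24 h, the membrane transporter SLC4A11 rose by 5.70 ± 0.36 on the log2 scale, from an intensity of 18.5 ± 9.6 in control to 1741 ± 213 (adjusted p = 0.00052). FXYD2, an ion transport regulator of the FXYD family, rose by 4.43 ± 0.37 from 4.2 ± 1.3 to 453 ± 214 (adjusted p = 0.0016). The small heat shock protein CRYAB rose by 3.08 ± 0.26, reaching an intensity of 13555 ± 610 from 1688 ± 683 (adjusted p = 0.0018); on 1 of the 24 h arrays it was the brightest probe set, so its rise may be understated. AKR1B1 rose by 1.67 ± 0.19, from 1181 ± 191 to 3822 ± 889 (adjusted p = 0.0038). The protease inhibitor SERPINA1 rose by 3.43, the acetyl-CoA synthetase ACSS2 by 3.32, the calcium-binding S100G by 3.30, the stress-induced NUPR1 by 3.20, LRRN1 by 3.09, AGFG2 by 3.04, the chemokine-scavenging receptor ACKR4 by 2.98, the complement receptor C5AR2 by 2.97 and DKK1 by 2.86. In control, SLC4A11, FXYD2, SERPINA1, S100G, LRRN1 and ACKR4 had mean intensities of 30.8 or less, so their log2 changes are understated.

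The cytokine IL6 fell most at 24 h among named genes, by 3.36 ± 0.59, from an intensity of 2410 ± 1067 to 253 ± 174 (adjusted p = 0.015). RRM2, the regulated subunit of ribonucleotide reductase, fell by 2.45 ± 0.17, from 3879 ± 705 to 698 ± 120 (adjusted p = 0.00077). The amino acid transporter SLC7A5 fell by 2.12 and SLC1A5 by 1.37. Genes of DNA replication and its control also fell, with log2 changes of -2.72 for CDCA7, -2.17 for UHRF1, -1.98 for the licensing factor CDC6, -1.97 for the polymerase subunit POLE2, -1.86 for MYBL2, -1.76 for the chromatin assembly factor CHAF1B and -1.75 for FBXO5. AGPAT5 fell by 1.84 and C18H19orf48 by 1.96. MYC was below control at 24 h also, having dropped by 1.58 ± 0.17 (adjusted p = 0.0038).

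**Figure D2:**
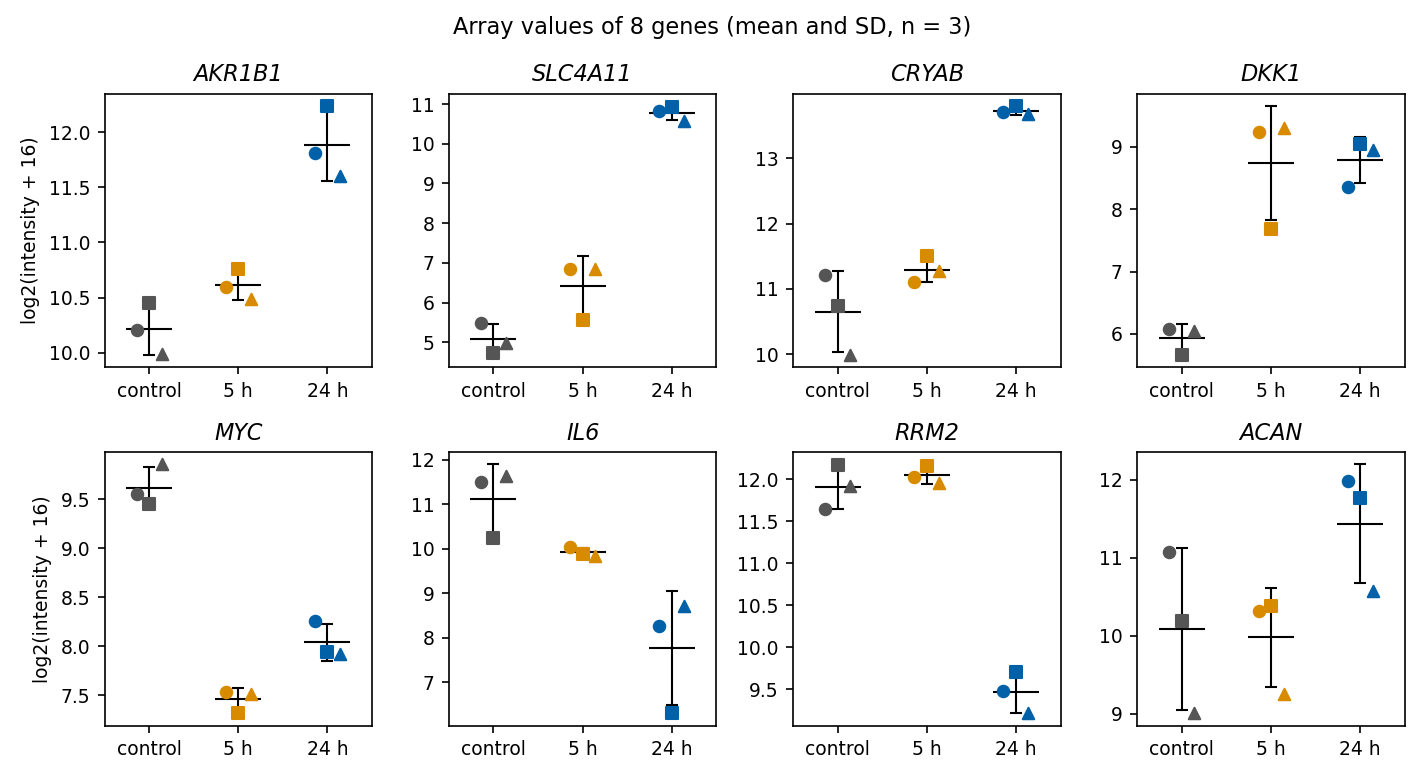
Log2(intensity + 16) on the y axis for 8 genes in control, 5 h and 24 h arrays on the x axis; points are arrays with the symbol giving the replicate number, and the bar and whiskers are the mean and SD of 3 arrays. SLC4A11, CRYAB and AKR1B1 were highest at 24 h, DKK1 was raised at 5 h and 24 h, MYC was lower at 5 h and 24 h, IL6 and RRM2 were lowest at 24 h, and the control arrays of ACAN spread with an SD of 1.04 around a mean of 10.09.

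DNA replication and G1/S genes fell at 24 h: 17 of 29 measured members were called, 0 rose, and the median log2 change was -1.09 (camera adjusted p = 1.0e-12, 0.38 with an estimated correlation). Beside RRM2, UHRF1, CDC6 and POLE2, the cyclin CCNE2 fell by 1.67 and the clamp loader subunit RFC2 by 1.09; with the replicate block 24 members fell, and 23 adjusted over the list alone. Mitosis and G2/M genes fell with a median of -0.80 (camera adjusted p = 7.7e-10, 0.57 with an estimated correlation), and 7 of 31 members were called, among them CCNA2 at -1.31, CENPN at -1.13, ASPM at -1.07 and CKS1B at -1.02; 26 fell with the replicate block and 14 adjusted over the list alone. Over these 2 lists the median change in replicate pairs 1, 2 and 3 was -0.61, -0.88 and -1.30. Ribosome biogenesis genes fell with a median of -0.77 (camera adjusted p = 2.8e-10, 0.38 with an estimated correlation); 10 of 24 were called, such as the nucleolar GTPase GNL3 at -1.502, fibrillarin (FBL) at -1.42, WDR43 at -1.08 and NOLC1 at -0.98. With the replicate block 23 fell, and 14 adjusted over the list alone. Of 46 cytosolic ribosomal protein genes 0 were called, with a median of 0.024 (camera adjusted p = 0.73), and the replicate block also called 0. Most of these probe sets lie near the top of the array range, so stable levels are not shown by this. The log2 ratio of 3-prime to 5-prime actin probe sets, a sign of RNA length, was 2.99 ± 0.28 at 24 h and 2.69 ± 0.18 in control (SD, 3 arrays each), and that of GAPDH was 0.025 ± 0.016 and -0.084 ± 0.092.

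Cholesterol synthesis genes rose at 24 h with a median of 0.78 (camera adjusted p = 7.0e-07, 0.38 with an estimated correlation). Of 16 members 5 were called, including TM7SF2 at 1.79, DHCR7 at 1.48, LSS at 1.26 and HMGCS1 at 0.84; 15 rose with the replicate block and 14 adjusted over the list alone. Osmoprotective genes rose with a median of 0.83 (camera adjusted p = 0.0042, 0.38 with an estimated correlation). Of 9 members 3 were called, AKR1B1, HSPA1A at 1.11 ± 0.25 and HSPH1 at 0.39 ± 0.10; 7 rose with the replicate block and 4 adjusted over the list alone. HSPA1A is uncertain, since of its 6 probe sets 3 rose and 2 fell at 24 h, and close relatives of the gene may share probes. With each of the 9 arrays left out in turn, the call of HSPH1 ended in 9 refits and that of HSPA1A in 5. SGK1, a kinase that regulates sodium transport, stood at 0.83 ± 0.24 with adjusted p = 0.063, and 0.0088 with the block. Interferon response genes rose with a median of 0.27 (camera adjusted p = 0.030, 0.38 with an estimated correlation); 5 of 18 were called over all probe sets and adjusted over the list alone, and 6 rose and 1 fell under the replicate block, including MX1 at 1.82, IRF9 at 1.72, ISG15 at 1.51 and IRF7 at 1.17.

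Cytokines, chemokines and NF-kB targets shifted up at 24 h with a median of 0.46 (camera adjusted p = 0.017, 0.48 with an estimated correlation). Of 32 members 5 rose and 2 fell, also when adjusted over the list alone, and 13 rose and 2 fell with the replicate block. PTGES, an enzyme of prostaglandin E synthesis, rose by 2.52, the mitochondrial superoxide dismutase SOD2 by 1.53 and CXCL3 by 1.18, while IL6 and CXCL12 (-0.74) fell. Genes of the unfolded protein and integrated stress response shifted down with a median of -0.22 (camera adjusted p = 0.049, 0.69 with an estimated correlation), with 4 of 25 down and 1 up, 6 down and 1 up adjusted over the list alone, and 10 down and 2 up under the replicate block. The members that fell included the serine synthesis enzymes PHGDH (-1.19) and PSAT1 (-1.15) and the endoplasmic reticulum protein SDF2L1 (-0.88), while the stress-induced transcription factor ATF3 rose by 1.99.

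Matrix genes moved in both directions at 24 h. In the cartilage-type list the hyaluronan and glycosaminoglycan enzymes CHSY1 (-0.96), UGDH (-0.80) and HAS2 (-0.73) fell among 15 members (camera adjusted p = 0.87). Aggrecan, ACAN, the main proteoglycan of the disc, stood at 1.35 ± 0.56 with adjusted p = 0.19, and 0.00041 with the replicate block, with a log2 SD between arrays of 1.04 in control and 0.76 at 24 h. COL2A1 stood at -0.39 ± 0.82 (adjusted p = 0.87). In the fibrous matrix list COL12A1 rose by 1.73 and DCN by 0.57 among 29 members (camera adjusted p = 0.095). Of 26 matrix proteases and inhibitors 3 rose, including TIMP2 (0.64) and CTSK (0.53), and 2 fell, PLAU (-0.91) and PLAUR (-0.70), with camera adjusted p = 0.74. Of 11 nucleus pulposus markers 2 fell, BNIP3 (-1.64) and CXCL12 (camera adjusted p = 0.12). Of 27 glycolysis and hypoxia genes 1 rose and 4 fell, among them TPI1 (-0.98), SLC16A3 (-1.19) and NDRG1 (-0.95), with camera adjusted p = 0.12. Of 26 genes of the actin cytoskeleton 3 fell and 1 rose, with FHL2 at -0.88, TPM1 at -0.45, ACTB at -0.27 and FHL1 at 0.995; the list's camera adjusted p was 0.10, and 0.029 with the replicate block, but 0.69 with an estimated correlation, and no list was called with both. Under the block the members that rose and fell were 5 and 4 for cartilage-type matrix, 10 and 4 for fibrous matrix, 9 and 8 for proteases and inhibitors, 1 and 3 for nucleus pulposus markers, 5 and 11 for glycolysis and hypoxia, and 3 and 10 for the actin cytoskeleton.

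The remaining lists were not called at 24 h. Of 25 oxidative stress genes 4 rose, including SOD2, GPX1 (0.99) and CAT (0.43), and PRDX1 (-0.45) fell, with camera adjusted p = 0.28. Of 22 heat shock genes CRYAB, HSPA1A and HSPH1 rose and HSPA8 (-0.83) and HSPD1 (-0.86) fell, also with camera adjusted p = 0.28. Of 9 amino acid transporters 2 fell, SLC7A5 and SLC1A5 (camera adjusted p = 0.28). Of 16 p53 targets BTG1 (0.88) and XPC (0.91) rose and PLK2 (-0.85) fell (camera adjusted p = 0.52), while CDKN1A stood at 0.27 ± 0.29 and GADD45A at -0.48 ± 0.41, neither called. Of 21 immediate early genes 4 rose, including ATF3, JUND (0.59) and IER3 (0.46), and MYC fell (camera adjusted p = 0.73). Of 17 sodium, potassium and chloride transport genes 0 were called (camera adjusted p = 0.87), with ATP1B1 at 0.078 ± 0.260. The taurine transporter SLC6A6, of the osmoprotective and amino acid transporter lists, stood at 0.11 ± 0.20. Its 1 probe set lay near the floor, at log2 values of 5.10 to 5.69 with the filter cut at 5.05, so a change may be understated. Of 22 genes of TGF-beta and BMP signalling, follistatin (FST) fell by 1.497 (camera adjusted p of the list 0.87), and of 17 in Wnt and Notch signalling DKK1 rose and FZD4 fell by 1.07 (camera adjusted p of the list 0.73). Mitochondrial oxidative phosphorylation had UQCRB at -0.57 and ATP5MC1 at -0.88 called among 40 (camera adjusted p = 0.086), and the 17 apoptosis regulators and 10 histone genes had 0 calls (camera adjusted p = 0.74 and 0.73). Under the block the members that rose and fell were 11 and 5 for oxidative stress, 4 and 10 for heat shock, 2 and 4 for amino acid transporters, 5 and 2 for p53 targets and 6 and 4 for immediate early genes. They were 1 and 2 for sodium, potassium and chloride transport, 5 and 4 for TGF-beta and BMP signalling, 1 and 2 for Wnt and Notch signalling, 2 and 9 for oxidative phosphorylation, 2 and 1 for apoptosis regulators and 1 and 4 for histones.

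**Figure D3:**
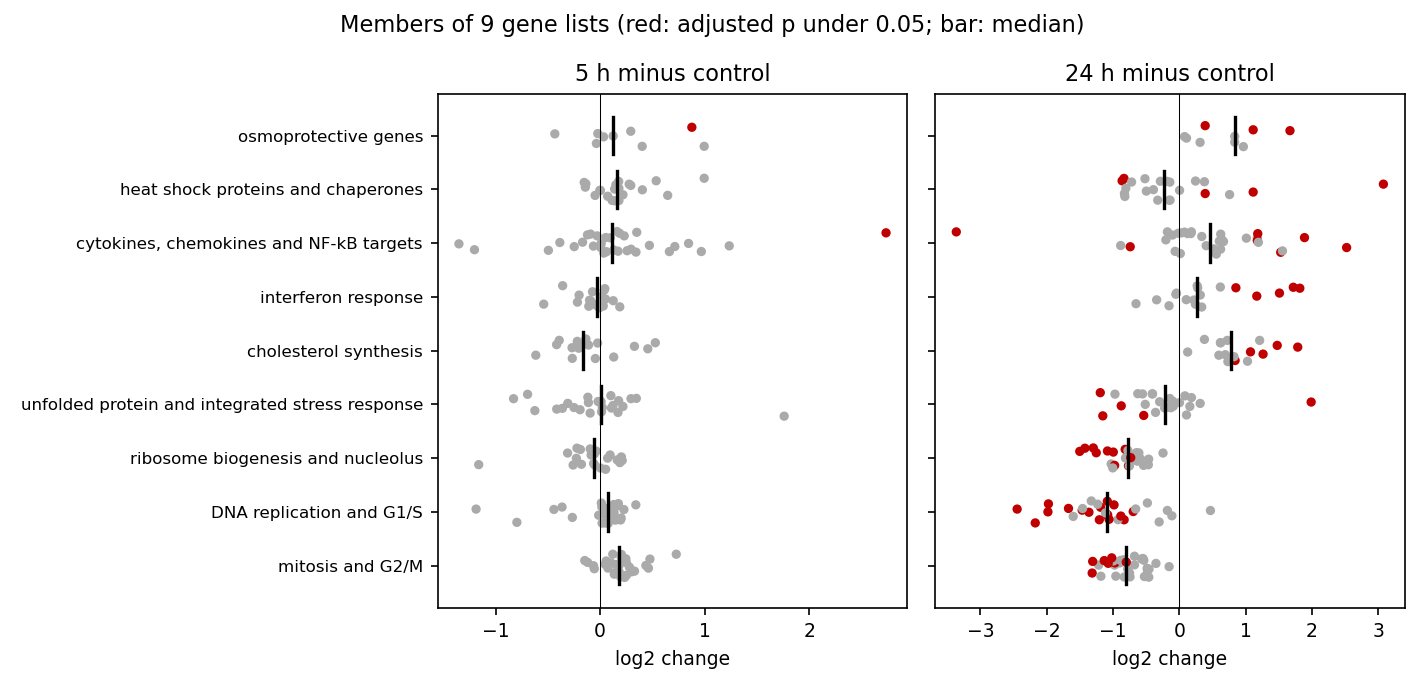
Log2 change on the x axis of each measured member of 9 gene lists, at 5 h minus control on the left and 24 h minus control on the right; red points have an adjusted p under 0.05, grey points do not, and the black bar is the list's median. At 24 h the medians were -1.09 for DNA replication, -0.80 for mitosis, -0.77 for ribosome biogenesis and 0.78 for cholesterol synthesis.

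None of the 6 tested marker lists of other cell types passed camera at either time point; the lowest adjusted p was 0.084 at 5 h and 0.087 at 24 h, both for macrophage and other leukocyte markers. Among 8 of these markers CD14 rose at 24 h by 1.43. Of 7 markers of annulus and tendon-type fibroblasts COL12A1 and THY1 (0.74) rose (camera adjusted p of the list 0.30), and of 5 skeletal muscle markers CKM rose by 1.99 (camera adjusted p of the list 0.73). Endothelial (camera adjusted p = 0.87), endplate (0.74) and pericyte (0.74) markers had 0 calls at 24 h. The erythroid, notochordal and adipocyte lists had under 5 measured members and 0 calls. Under the block the markers that rose and fell at 24 h were 2 and 0 for leukocytes, 3 and 3 for annulus fibroblasts, 2 and 1 for skeletal muscle, 3 and 1 for endothelium, 0 and 0 for endplate, 0 and 1 for pericytes and 1 and 1 for adipocytes.

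In all, 771 probe sets were higher and 779 lower at 24 h than in control, and with the replicate block 3302 and 3150, which included each of the 1550. The total was 310 without control replicate 2, 460 without control replicate 3, 304 without 24 h replicate 1, 767 without 24 h replicate 2, 898 without 5 h replicate 1 and 900 without 24 h replicate 3. With each array centred on its median, 503 were higher and 827 lower. Of 89 genes named for 24 h and called there, 37 kept their call with each array left out in turn, among them SLC4A11, FXYD2, CRYAB, AKR1B1, RRM2, CCNE2, GNL3, PTGES, MX1 and MYC; IL6 lost it without control replicate 3 (adjusted p = 0.053). The list calls ended for cytokines without control replicate 2 or 24 h replicate 3 (highest adjusted p = 0.069), for the interferon response without 24 h replicate 2 (0.061), and for the unfolded protein response without any of control replicates 1 and 3, 5 h replicate 2 and 24 h replicates 2 and 3 (0.24).

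Comparing the time points directly, SLC4A11 was higher at 24 h than at 5 h by 4.35, FXYD2 by 4.14, ACSS2 by 3.65, SERPINA1 by 3.45, S100G by 3.19, C5AR2 by 3.06, LRRN1 by 2.98 and the cyclooxygenase PTGS1 by 2.93 on the log2 scale. The values on the lower side were -2.58 for RRM2, -2.45 for SEMA4A, -2.29 for UHRF1, -2.28 for CDCA7, -2.16 for IL6, -2.07 for MYBL2, -2.03 for SLC7A5 and -2.03 for POLE2. AKR1B1 was higher by 1.27 (adjusted p = 0.0052) and SGK1 by 0.86 (adjusted p = 0.043), while a dimmer SGK1 probe set at 0.83 was not called (adjusted p = 0.061). ACAN stood at 1.46 with adjusted p = 0.12, and 0.00020 with the replicate block, and GADD45A at -1.09 with adjusted p = 0.11, and 0.029 with the block. DKK1 was at the same height at both times within its error, with a difference of 0.048 ± 0.417.

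Of the lists, DNA replication (20 of 29 lower, median -1.13, camera adjusted p = 3.2e-12), mitosis (14 of 31 lower, -0.93, 3.2e-12) and ribosome biogenesis (9 of 24 lower, -0.67, 5.8e-08) were lower at 24 h than at 5 h. Cholesterol synthesis was higher (9 of 16, median 0.78, adjusted p = 7.3e-06). With an estimated correlation, adjusted p was 0.55 for these 4 lists. Heat shock genes were lower, with 7 of 22 down and 1 up (adjusted p = 0.020, 0.56 with an estimated correlation), and so were genes of mitochondrial oxidative phosphorylation, 3 of 40 (0.029, 0.68 with an estimated correlation). Fibrous matrix genes were higher, 3 of 29 (0.020, 0.60 with an estimated correlation), as were interferon response genes, 6 of 18 (0.034, 0.55 with an estimated correlation and 0.052 with the replicate block). The actin cytoskeleton list had adjusted p = 0.12, and 0.042 with the block, but 0.62 with an estimated correlation, and no list was called with both. Adjusted over the list alone, the counts were 22 lower for DNA replication, 27 lower for mitosis, 12 lower for ribosome biogenesis and 11 higher for cholesterol synthesis. Under the replicate block they were 25 lower for DNA replication, 29 lower for mitosis, 19 lower and 1 higher for ribosome biogenesis, 13 higher for cholesterol synthesis, 14 lower and 4 higher for heat shock, 15 lower and 2 higher for oxidative phosphorylation, 15 higher for fibrous matrix, and 9 higher and 2 lower for the interferon response.

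Between 24 h and 5 h, 1443 probe sets were higher and 1108 lower, and with the replicate block 4353 and 3531. With arrays centred on their medians the split turned to 806 higher and 1608 lower. The total was 854 without 5 h replicate 1, 1393 without 5 h replicate 2, 940 without 24 h replicate 1, 1616 without 24 h replicate 2 and 1677 without 24 h replicate 3. Of 18 genes named for this comparison or fixed by name and called in it, 15 kept their call with each array left out in turn. Of the lists, heat shock lost its call without 5 h replicate 2 (adjusted p = 0.058), fibrous matrix and oxidative phosphorylation without 5 h replicate 2 or 24 h replicate 3 (highest 0.10 and 0.11), and the interferon response without 5 h replicate 2 or 3 or 24 h replicate 2 (0.075).

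Of the 42 probe sets higher at 5 h, 16 were also higher at 24 h, against 1.80 for independent lists, and of the 45 lower at 5 h, 8 were also lower at 24 h, against 1.95. Another 2 that were lower at 5 h were higher at 24 h. The 24 shared calls became 46 without 5 h replicate 2 and between 5 and 12 without any other array. Both comparisons use the same control arrays. With the replicate block 217 were shared upward (81.0 for independent lists) and 130 downward (107 for independent lists), while 108 were lower at 5 h and higher at 24 h and 15 the reverse. No value for independent lists was computed for calls in opposite directions, so their counts are not read as reversals. Across probe sets, which are not independent replicates, the 5 h and 24 h changes correlated at r = 0.14, with a covariance of 0.023. In simulation of unchanged groups, shared controls alone gave r = 0.50. Changes that occur at only 1 of the times lower r, so these values of r do not show a direction. Shared controls alone gave a simulated covariance of 0.061 with the spread within groups and 0.014 with the spread left after the block. The former drew arrays independently, although same-numbered arrays deviate alike, so it does not match the pairing. The 3 control arrays were too few to split, and part of the shared calls may come from them. The simulations gave 0.02 shared calls on average and at most 1. No probe set changed in them, so they do not bound that part.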

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

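The test chosen only after its result was seen was that of control replicate 1. The other tests in this part were fixed beforehand, those of the arrays numbered 3 after the pattern itself was known. A condition on the spread of the RNA quality ratios at 24 h was not in the bound written beforehand. Likewise, the bound written for control replicate 1 did not hold the condition that left it open. Groups of 3 arrays were not tested for outliers.

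Genes named for either time point or for 24 h minus 5 h are given here where the test of 24 h minus 5 h itself passed (limma adjusted p under 0.05). This held for 94 genes and, by camera, for 6 of the lists called at either time. Genes named for 24 h minus 5 h were picked by passing it, so passing is no further support for them. The others were picked on comparisons that share arrays with this test, so part of a return toward control may come from the selection. Of these genes, 42 were higher at 24 h. Their log2 values at 24 h minus 5 h were 4.35 for SLC4A11, 4.14 for FXYD2, 3.65 for ACSS2, 3.45 for SERPINA1, 3.19 for S100G, 3.06 for C5AR2, 2.98 for LRRN1, 2.93 for PTGS1, 2.47 for ACKR4, 2.43 for CRYAB, 2.40 for TM7SF2, 2.39 for AGFG2, 2.23 for PTGES and 2.08 for IRF9. Further values were 1.97 for NAT1, 1.86 for MX1, 1.82 for KCTD11, 1.76 for CD14, 1.74 for ANKRD49, 1.73 for ISG15, 1.59 for DHCR7, 1.55 for BHLHE40, 1.53 for LSS, 1.42 for COL12A1, 1.34 for SOD2, 1.27 for AKR1B1, 1.26 for HMGCS1 and 1.12 for XPC. The remaining higher genes stood at 1.12 for IRF7, 0.93 for LFNG, 0.92 for FHL1, 0.86 for SLC20A1, 0.86 for SGK1, 0.84 for LIPT1, 0.84 for CNOT6, 0.83 for GPX1, 0.75 for DICER1, 0.71 for CTSK, 0.69 for TIMP2, 0.66 for THY1, 0.62 for DCN and 0.43 for CAT. Of these, NAT1, KCTD11, ANKRD49, BHLHE40, LFNG, SLC20A1, LIPT1, CNOT6 and DICER1 had fallen at 5 h against control.

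The other 52 genes were lower at 24 h than at 5 h. Their log2 values at 24 h minus 5 h were -2.58 for RRM2, -2.45 for SEMA4A, -2.29 for UHRF1, -2.28 for CDCA7, -2.16 for IL6, -2.07 for MYBL2, -2.03 for SLC7A5, -2.03 for POLE2, -1.82 for BNIP3, -1.81 for AGPAT5, -1.62 for CDC6, -1.60 for FBXO5, -1.58 for MEOX2 and -1.52 for FBL. They were followed by -1.44 for CCNA2, -1.43 for CENPN, -1.43 for GNL3, -1.42 for NFIL3, -1.37 for CHAF1B, -1.35 for CKS1B, -1.29 for WDR43, -1.23 for ASPM, -1.22 for OSR2, -1.20 for FST, -1.16 for SLC1A5, -1.13 for PSAT1, -1.11 for TPI1 and -1.08 for PHGDH. Smaller differences were -1.08 for IP6K2, -1.05 for SDF2L1, -1.03 for NOLC1, -1.03 for HSPD1, -1.01 for SLC16A3, -0.96 for HAS2, -0.93 for CHD2, -0.92 for ATP5MC1, -0.91 for UGDH, -0.87 for CCNE2, -0.82 for RFC2, -0.79 for CXCL12, -0.79 for HSPA8 and -0.79 for NDRG1. The smallest were -0.72 for PLAUR, -0.66 for FZD4, -0.66 for UQCRB, -0.65 for FHL2, -0.58 for PNRC1, -0.56 for SLC38A2, -0.53 for CHSY1, -0.38 for TPM1, -0.35 for PRDX1 and -0.27 for ACTB. MEOX2, NFIL3, OSR2, IP6K2, SEMA4A, CHD2, PNRC1 and SLC38A2 had risen at 5 h against control. IP6K2 is uncertain, since another of its probe sets was higher at 24 h than at 5 h, by 0.89 (adjusted p = 0.043), and SEMA4A had a second probe set at -0.67 (adjusted p = 0.16). The 6 lists had median log2 changes at 24 h minus 5 h of -1.13 for DNA replication and G1/S, -0.93 for mitosis and G2/M, -0.67 for ribosome biogenesis, -0.38 for heat shock proteins, 0.30 for the interferon response and 0.78 for cholesterol synthesis. With an estimated correlation none of these list calls remained (adjusted p = 0.55 to 0.56), and that of the interferon response ended with the replicate block also (0.052). Fibrous matrix (median 0.32) and oxidative phosphorylation (-0.16), called at neither time against control, differed between the times too, again not with an estimated correlation. Among 45 bacterial control probe sets, which the comparisons above do not use, 0 were called at 5 h or 24 h by limma, with lowest adjusted p of 0.99 and 0.87.

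The 3 arrays numbered 3, 1 of each group, stood apart from the other 6, with 3573 probe sets higher and 4527 lower at adjusted p under 0.05, and 4785 higher and 3882 lower after quantile normalization. A difference of array scale or overall hybridization is argued against as the whole cause, because the number differing after quantile normalization was 107% of that in the deposited values, although the hybridization control bioB had intensities of 240.7, 271.3 and 260.4 on these arrays and at least 376.3 on the others. RNA quality stays open: of the 6 ratios of 3-prime to 5-prime signal for actin and GAPDH on these arrays, 1 lay outside the range of the other arrays. Another cell type may be present and stays open too, as the highest median difference of a marker list was 0.48, for 5 skeletal muscle markers, with camera adjusted p = 0.092. The design names no difference between the replicate numbers, so no further biological explanation was tested, and different animals remain possible.

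DNA replication and mitosis genes were lower at 24 h than in control, with 17 of 29 and 7 of 31 members called, but the lists did not pass camera with an estimated correlation (adjusted p = 0.38 and 0.57). Array scale is argued against, since the median change over the 60 genes of both lists was -0.93 after quantile normalization and -0.94 before it. A fall carried by a single culture is argued against as well, since the smallest fall among the 3 replicate pairs was -0.61. RNA quality cannot be excluded. The log2 actin ratio of 3-prime to 5-prime signal was higher at 24 h by 0.2999 on average over 3 pairs, with pairs at 0.32, -0.038 and 0.62. That of GAPDH was higher by 0.11, with pairs at 0.0060, 0.22 and 0.10. Both means lay within 0.3 of 0, the bound set beforehand as speaking against this cause, but actin only just. It was left open by a condition not in that bound, that the mean plus its SE lie within 0.3 too, which actin did not meet. Salt for 24 h is the difference the design names, and an effect of it on these genes stays among the open explanations. No untreated array is labelled with a time, so time in culture cannot be told apart from salt here and stays open too.

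More probe sets differed between 24 h and 5 h (2551) than between 24 h and control (1550). This order turned without 5 h replicate 1 (854 and 898) and without 5 h replicate 2 (1393 and 1533), and held without any other array. Control replicate 1, whose component 2 score lay toward the 24 h arrays, stays open as a reason. Without it 1420 were called for 24 h against control, below 1550, which met the bound written as speaking against this cause. It was left open by a condition not in that bound, that the count not exceed those without the other control arrays. These were 310 without control replicate 2 and 460 without control replicate 3, and leaving out an array costs power. Early changes running opposite to late ones may contribute, but the test did not settle it. The covariance of the 5 h and 24 h changes less that simulated for shared controls was 0.0092 with the spread left after the replicate block and -0.038 with the spread within groups. The latter simulation drew arrays independently, against their pairing by number, so only the former matches the arrays. A covariance over all probe sets does not show whether some of them run opposite. These explanations cannot be told apart further with 3 control arrays.

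For each comparison of groups, the 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For 5 h against control, 1 of the 10 splits, the real one, called as many probe sets (87), and the highest of the others called 0. For 24 h against control, 1 of 10 did so (1550, highest other 0), and for 24 h against 5 h, 1 of 10 (2551, highest other 0). The arrays are paired by number, and 4 of the 10 splits, the real one included, part all 3 pairs, while the other 6 part 1.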

How the results depend on the processing

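The settings chosen only after the data were seen were leaving out all 3 arrays numbered 3 and joining the estimated correlation to the replicate block. All other settings were fixed beforehand. Counts are given as higher and lower probe sets at 5 h against control, 24 h against control and 24 h against 5 h, where reported as 42 and 45, 771 and 779, and 1443 and 1108. Only counts outside 1.5 times the reported value are given, and except where the setting's construction shows it (fewer probe sets, arrays or residual degrees of freedom, a higher threshold), the cause was not tested.

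With the replicate block the counts were 442 and 614, 3302 and 3150, and 4353 and 3531, the shared calls of both times 347 where 24 had been reported, and the lists moved at 5 h 2 where 4 had been. The block ended 3 list calls, called the actin list at 24 h and between the times, and ended no call of a named gene. It gave a call to 6 results of 5 genes that the report prints as not called, and to further results not printed there, such as SLC4A11 at 5 h (adjusted p = 0.016). With array weights the counts were 197 and 348, 2122 and 1956, and 4774 and 3434; the weights did not fully converge. Fitted to the 6 arrays compared they were 7 and 6 at 5 h and 406 and 386 at 24 h, and the calls of 19 named genes at 5 h and 18 at 24 h ended. With arrays centred on their medians, 23 were lower at 5 h, 503 higher at 24 h and 806 higher at 24 h than at 5 h; the share of higher calls moved from 48.3% to 59.6%, from 49.7% to 37.8% and from 56.6% to 33.4%, and the calls of 7 named genes at 5 h and 8 at 24 h ended. After quantile normalization 27 were lower at 5 h. With 1 probe set per gene there were 16 and 21 at 5 h, and 835 and 724 for 24 h against 5 h. At a change of at least 2-fold, 396 and 315 remained of the calls at 24 h and 736 and 399 between the times. A pseudocount of 1, no filter, a filter at the 50th percentile, eBayes without trend, and leaving out probe sets with shared probes kept each of these counts within 1.5 times.

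Lists called at 5 h, 24 h and between the times were 4, 8 and 8 as reported, and 0, 0 and 0 with an estimated correlation, with or without the replicate block. After quantile normalization 5 lists differed between the times, the calls of heat shock, interferon response and oxidative phosphorylation having ended, as did that of the unfolded protein response at 24 h. The mean of all probe sets of a gene ended the call of the osmoprotective genes at 5 h and at 24 h (adjusted p = 0.071 and 0.078) and of the unfolded protein response at 24 h (0.096). Without the arrays numbered 3, 2 lists moved at 5 h; the counts of probe sets stayed within 1.5 times, and the calls of 12 named genes at 5 h and 15 at 24 h ended. Without a trend in eBayes 2 and 12 ended, and other settings ended at most 5. The filter at the 50th percentile removed some named genes, which were not tested there, leaving 30 followed at 5 h and 85 at 24 h.

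With each array left out in turn, the counts ranged from 8 to 49 higher and 7 to 77 lower at 5 h, from 161 to 752 higher and 138 to 781 lower at 24 h, and from 484 to 1354 higher and 370 to 1075 lower between the times. The shared calls ranged from 5 to 46, and the lists moved at 5 h from 2 to 5 and those differing between the times from 5 to 12. A call of a named gene was lost in 376 of these refits taken over genes and arrays, and kept its direction there.

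Among the results followed through the settings, signs turned for genes without a call and for mitosis at 5 h, and the cause was not tested. The refits with an array left out had no replicate block. Leaving out an array there breaks a pair, which can move a group mean by the offset of its replicate number. At 5 h with an array left out, SGK1 ranged from -0.27 to 0.11, ACAN from -0.65 to 0.38, COL2A1 from -1.10 to 0.21, SLC6A6 from -0.019 to 0.28, CDKN1A from -0.14 to 0.43 and the mitosis median from -0.048 to 0.33. At 24 h ATP1B1 ranged from -0.083 to 0.26, COL2A1 from -1.12 to 0.31 and SLC6A6 from -0.036 to 0.26. In order of replicate number, COL2A1 had log2 values of 8.43, 7.59 and 5.81 in control and 7.89, 7.29 and 5.50 at 24 h, lower in each pair. ATP1B1 had 10.70, 10.66 and 11.22 in control and 10.87, 10.69 and 11.26 at 24 h, slightly higher in each pair. Neither gene was called. Between the times COL2A1 ranged from -0.59 to 0.68, SLC6A6 from -0.12 to 0.12, HSPA1A from -0.11 to 0.29, ATP1B1 from -0.42 to 0.034 and CDKN1A from -0.0011 to 0.34. With arrays centred, SGK1 at 5 h was 0.062 and HSPA1A between the times -0.036. With array weights COL2A1 was 0.11 at 24 h and 0.33 between the times, and SLC6A6 0.11 between the times. Without the arrays numbered 3, SGK1 was 0.082 and CDKN1A -0.19 at 5 h, and SLC6A6 0.017 and COL2A1 0.11 between the times. Signal over background limits dim probe sets: between 22.7% and 25.9% of the probe sets of an array lay under the pseudocount of 16.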

Other observations

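The pattern weighed here was known before its test was chosen, and the test's bounds were set before its value was computed. The genes in this part were picked after their values were seen.

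The arrays numbered 3 differed from the other 6 in many transcripts. On the log2 scale, ABCF2 was lower by -3.88, the growth factor TGFB1 by -3.31, the lectin COLEC11 by -3.25, COL6A2 by -3.08, the glycolytic enzyme PKM by -2.98 and SOX10 by -2.94. Higher on these arrays were the poly(A)-binding protein PABPN1 by 2.17, WASL by 1.90, HOXA5 by 1.59, the splicing-associated PNISR by 1.45 and the chemokine CCL20 by 1.41. None of the 32 tested gene and marker lists passed camera for this difference, while 8100 single probe sets passed limma.

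A hypothesis is that labelling or amplification on the arrays numbered 3 depended on the probed part of a transcript. Across 2217 genes with at least 2 single-gene probe sets, which are not independent replicates, the differences of the 2 brightest probe sets correlated at r = 0.30 for arrays numbered 3 against the rest and at r = 0.77 for 24 h minus control, although the spread of both differences was alike (SD 0.53 and 0.54). The former r was 38.9% of the latter, below the 50% set as what this cause would give, and among the 855 genes with both probe sets bright the values were 0.34 and 0.87. This is consistent with a technical origin of part of the difference, but sequence variants of another animal under the probes, which were not tested here, may give the same result.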
